A study of Homo sapiens with 8 samples.

How the data were processed

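ATAC-seq was done on G401 cells with doxycycline-inducible SMARCB1 (1 µg/ml doxycycline, per the labels), with 2 replicates on each of days 0, 1, 3 and 7. Groups were taken from the sample titles. Nothing in the labels says whether the replicates came from separate cultures. The sources used here are the sample labels and 1 deposited file of narrowPeak layout, which joins 4 peak lists with 411408 peaks in all. Bowtie2, deepTools and MACS2 version 2.1.1.20160309, and the genome build hg19, are named in the submitters' processing notes. The alignment and duplicate filters, any transposase offset applied to the reads, and whether the replicates of a day were pooled before calling are not given in the sources used here. The names of 3 lists match days 1, 3 and 7 in the labels. The 4th list, whose abbreviation the labels do not spell out, was taken as day 0 by elimination, and every statement about day 0 rests on that.

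Per peak, the deposited list gives the authors' score, which equals 10 times the -log10 q cut to a whole number in 100% of peaks. The fold, a ratio of the summit to the local background of the same list, is the authors' value and was used only to rank and filter peaks within a list, apart from the comparisons of fold named as such. The deposited -log10 p and -log10 q (p-value and q-value) are those of the authors' peak caller, and the smallest -log10 q was 2.44, 2.06, 2.01 and 2.19 on days 0, 1, 3 and 7. The deposited summit position is an offset in bp from the start of the peak, another value of the authors' caller. In each list 185 to 196 peak numbers were missing, 0.165% to 0.242% of those called, in the largest runs near centromeres (for example 14 between 38743654 and 42672235 on chromosome 10 in the day 0 list). Some peaks had therefore been removed before deposit, by a filter that is not given in the sources used here.

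The number of reads at each summit was recovered from fold and -log10 p together, taking fold as (reads + 1) / (background + 1) and p as the Poisson chance of more reads than observed. A single whole number of reads fitted each of the 411408 peaks within 0.005 in -log10 p, with the next best whole number off by at least 0.0272. The background most often shared by the peaks of a list (18.5% to 20.9% of peaks) was taken as its genome-wide background: 6.34, 6.04, 6.73 and 6.10 reads on days 0, 1, 3 and 7. This is the measure of depth used here. All other backgrounds were multiples of the step that whole reads in a window of 10000 bp give with an extension of 200 bp. Median summits held 57, 51, 52 and 48 reads and the smallest 18, 16, 17 and 18, so single weak peaks carry wide counting error. Scaled summits are summit reads divided by the genome-wide background. The recovery was tested on 16856 simulated peaks and returned the reads of 100% of them, and the assignment of regions to days returned all of 5000 simulated regions.

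Peaks were compared with bedtools 2.31.1, counting an overlap of at least 1 bp. Shares have exact Clopper-Pearson 95% intervals, and ratios of summit reads have exact conditional binomial 95% intervals after scaling for depth. The intervals of shares treat peaks or regions as independent draws and hold no error from the read counts. The intervals of ratios cover counting error only, and reads that are PCR copies of 1 molecule would make them too narrow. Counting error between lists was also simulated by redrawing summit reads from Poisson distributions 20 times at the depth of the other list. That simulation does not model the choice of peaks just above the limit or the minimum peak width. Merged regions are unions of overlapping peaks, and each day's value is that of its highest summit there. Random draws for groups of regions took the same number per chromosome from all merged regions, 1000 times. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used matplotlib 3.10.9. Coordinates are 1-based hg19.

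The comparison of peak sets, the count and covered length per list, the alternatives of a stricter score or q, reciprocal overlap and the upper part of each list, and the rule for named regions were fixed before the data were examined. That rule names the 10 peaks with the highest fold in each list. The fold limit of 6 was chosen after counts at limits of 4, 5, 6 and 7 had been seen, and the analyses of merged regions, summit heights, time course steps, groups of regions, chromosomes and distances were also added after seeing the data, as were all other named regions. Tests per region across the 8 samples had been planned and could not be made, since peak lists hold no value per sample. The share of regions at promoters, the AP-1 motif share and gene lists needed a genome and annotation in hg19. The reference at hand is a gene table of GRCh38, so these were not analysed here, nor were the SMARCB1 and AP-1 genes themselves.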

Results

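Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in G401 cells, an established line from a rhabdoid tumour of the kidney that lacks SMARCB1, a core subunit of the SWI/SNF chromatin remodelling complex. The cells carried an inducible SMARCB1 and were sampled without induction (day 0, labelled SMARCB1 -/-) and after 1, 3 and 7 days of doxycycline (labelled SMARCB1 +/+). The 8 samples form 4 groups of 2 replicates, but the deposited values are 1 peak list per day, so no difference between days has a replicate error or a p-value here. Intervals given below are 95% intervals. Those of shares treat peaks or regions as independent draws, and those of summit ratios cover the counting error of reads only. Neither kind covers the spread between replicates. The lists held 80744 peaks on day 0, 109876 on day 1, 117606 on day 3 and 103182 on day 7. The list named with neither a day nor the drug was taken as day 0, because it was the only list left once the other 3 had been matched to the 3 induced days. The depth behind the lists was similar: the genome-wide background was 6.34 reads per position on day 0, and the backgrounds of days 1, 3 and 7 were 0.953, 1.06 and 0.962 times that value.

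The first comparison asked how much of the genome was called accessible before and after SMARCB1 was restored. More regions were called on every induced day than on day 0, with 1.36 times as many peaks on day 1, 1.46 times on day 3 and 1.28 times on day 7. Called peaks covered 48.5 Mb on day 0, 65.6 Mb on day 1, 70.0 Mb on day 3 and 60.8 Mb on day 7. Peak shape changed little, since the median width was 454 bp on day 0 and 467, 471 and 463 bp on days 1, 3 and 7. The median of the authors' fold enrichment, which sets a peak's summit against its local background in the same list, was 3.81, 3.83, 3.77 and 3.87 on days 0, 1, 3 and 7. Days 1 and 7 had longer lists than day 0 at a slightly lower depth.

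The most enriched regions by fold were shared by all 4 lists. Fold is a ratio to the local background, so these need not be the highest summits. The peak ranked 2 on day 0 held 131 reads, against 283 at the largest day 0 summit. The 10 peaks with the highest fold in each list came from 15 distinct regions, and all 40 of these peaks overlapped a peak in each of the other lists. The region at chromosome 7, 74508426 to 74509276 (hg19), had the highest fold on day 0 at 19.5, and its peaks reached 18.8 on day 1, 19.8 on day 3 and 20.2 on day 7. The day 1 list was led by chromosome 7, 74267054 to 74267725, with a fold of 20.3, which was 16.9 at the overlapping day 0 peak. Further regions among the 10 highest in every list were chromosome 9, 68726005 to 68726712, with a day 0 fold of 18.0, chromosome 15, 74392182 to 74392876, with 17.6, chromosome 1, 146009232 to 146010071, with 16.8, and chromosome 7, 72649216 to 72649908, with 16.5. The coordinates of these 4 are those of the day 0 peaks. Genes at these positions were not analysed here, because the annotation at hand belongs to another genome build. Whether reads map uniquely at these positions was not examined either, so a high fold there need not mean high accessibility.

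The second comparison asked which accessible regions were kept, gained and lost from day 0. Most day 0 peaks were kept: 87.0% (86.8 to 87.2) overlapped a day 1 peak, 85.4% (85.1 to 85.6) a day 3 peak and 82.5% (82.2 to 82.8) a day 7 peak. New peaks, which overlapped no day 0 peak, made up 36.6% (36.3 to 36.9) of the day 1 list, or 40217 peaks, 41.8% (41.5 to 42.1) of the day 3 list, or 49181 peaks, and 35.6% (35.3 to 35.9) of the day 7 list, or 36734 peaks. Against these, 10494, 11796 and 14129 day 0 peaks had no counterpart on days 1, 3 and 7. The Jaccard index of covered bases with day 0 was 0.592 on day 1, 0.541 on day 3 and 0.588 on day 7. Redrawing the reads of unchanged peaks left 3.72% of day 1 peaks, 5.09% of day 3 peaks and 3.58% of day 7 peaks under the limit of the day 0 list. The same redrawing of day 0 peaks left 2.99%, 1.92% and 3.38% under the limits of days 1, 3 and 7, against the 10494, 11796 and 14129 of 80744 observed. These simulated shares are too low for weak peaks, because they leave out the choice of peaks just above the limit and the minimum peak width. Lost peaks were weak and narrow, with median folds of 2.89, 2.89 and 2.92 on days 1, 3 and 7. Their median widths were 258, 264 and 265 bp. New peaks had median folds of 3.27, 3.30 and 3.38 and median widths of 335, 358 and 339 bp on days 1, 3 and 7. Day 0 peaks that were kept had median folds of 4.11, 4.17 and 4.22. How far losses, and gains of weak peaks, exceed counting error was therefore not settled. The spread between replicates, which would be the proper yardstick, was not measurable from 1 list per day.

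**Figure D1:**
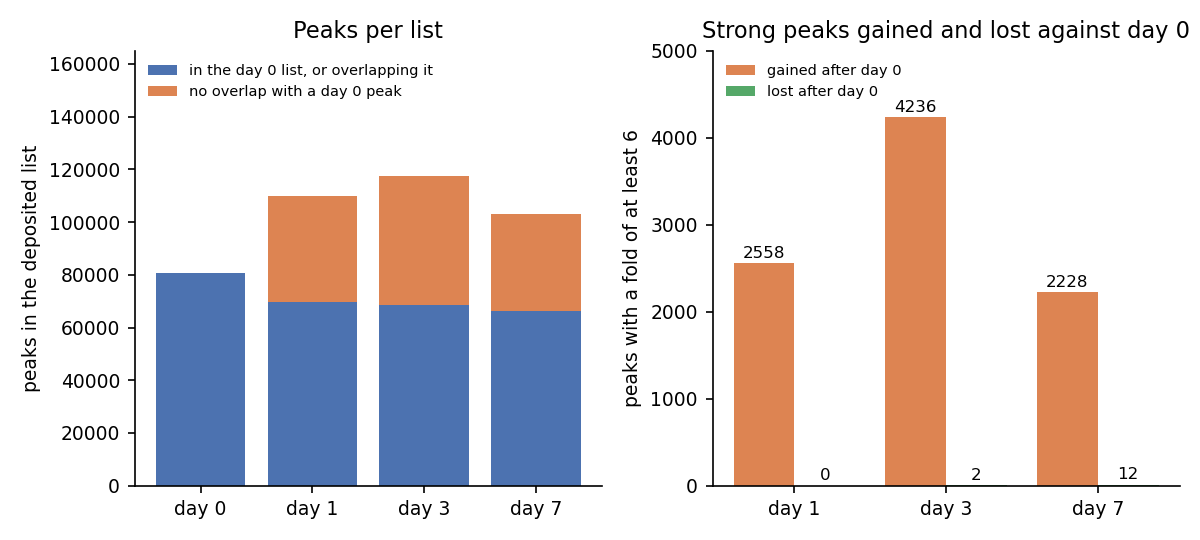
Left, number of peaks in each deposited list, with the part that overlaps no day 0 peak in orange (40217, 49181 and 36734 peaks on days 1, 3 and 7). Right, number of peaks with a fold of at least 6 that were gained or lost against day 0, with 2558, 4236 and 2228 gained and 0, 2 and 12 lost; each list is 1 set of peaks, so there are no error bars.

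Among strong peaks, defined by a fold of at least 6 in their own list, gains far outnumbered losses. On day 1, 2558 of 22130 strong peaks (11.6%, 11.1 to 12.0) overlapped no day 0 peak, on day 3 4236 of 21417 (19.8%, 19.2 to 20.3), and on day 7 2228 of 19229 (11.6%, 11.1 to 12.0). Of the 16548 strong day 0 peaks, 0 lacked a counterpart on day 1, 2 on day 3 and 12 on day 7. The near absence of losses depended on the limit, since a fold of at least 4 gave 429, 535 and 866 lost on days 1, 3 and 7 against 10105, 14599 and 10302 gained, and a fold of at least 5 gave 33, 39 and 120 lost against 5023, 7805 and 4765 gained. With a fold of at least 6 and a reciprocal overlap of at least 50%, 73, 108 and 93 were lost. The pair lost by day 3 lay at chromosome 5, 60351285 to 60351645, with a fold of 6.54, and chromosome 20, 2401891 to 2402268, with a fold of 6.40. The highest of the 12 lost by day 7 lay at chromosome 7, 149015066 to 149015625, with a fold of 7.75, and chromosome 16, 88281139 to 88281720, with a fold of 7.41. At the latter the summit was at 0.907 of day 0 on day 1 (0.611 to 1.34) and 0.831 on day 3 (0.561 to 1.23), while its local background was 2.07 and 2.61 times that of day 0. When strength was set by a summit of at least 10 times the genome background instead of by fold, 5915, 7699 and 3633 peaks were gained and 947, 1138 and 1366 were lost on days 1, 3 and 7. The lost peaks under that limit had a median fold near the low end, at 1.98, 2.00 and 1.98, and a median width of 268, 280 and 273 bp.

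The regions with the highest folds among those gained on all 3 induced days had no day 0 peak and reached folds above 10 within 1 day. They were chosen after their values were seen, ranked on the lowest of their 3 folds. At chromosome 8, 99865435 to 99866130, the fold was 12.0 on day 1, 11.4 on day 3 and 12.5 on day 7, with 117, 126 and 93 reads at the summit. At chromosome 2, 191906255 to 191907005, the folds were 10.9, 12.3 and 10.9. Chromosome 4, 73001776 to 73002669, had folds of 12.1, 11.7 and 10.8, and chromosome 6, 88153868 to 88154847, had 13.2 on day 1 and 10.6 on day 7. Chromosome 2, 79944359 to 79945278, chromosome 3, 159429227 to 159430097, and chromosome 13, 63187658 to 63188640, followed with day 3 folds of 10.5, 11.8 and 11.4. Regions found in 1 list alone had lower folds on every day. The highest was 5.45 on day 0, at chromosome 15, 79007245 to 79007573, where the summit held 45 reads, and 5.54, 6.86 and 6.61 on days 1, 3 and 7.

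The third comparison followed regions over the whole time course. Merging the 4 lists gave 146099 regions, of which 60786 (41.6%) had a peak on every day. A further 19074 (13.1%) had no day 0 peak and a peak on all 3 induced days, and 6227 (4.26%) had a peak on day 0 alone. Regions seen in only 1 induced list numbered 9780 on day 1, 14215 on day 3 and 7694 on day 7, with median widths of 255, 265 and 256 bp against 742 bp for regions present on every day, which merge peaks of 4 lists. Of the 67520 regions without a day 0 peak, 57.7% (57.3 to 58.1) were first seen on day 1, 30.9% (30.5 to 31.2) on day 3 and 11.4% (11.2 to 11.6) on day 7. Among the 4899 of these with a fold of at least 6 on any day, 4673 (95.4%) already had a day 1 peak of any fold. Another 224 were first seen on day 3 and 2 on day 7. A region first seen on day 7 had only 1 list in which to reach a fold of 6. The 2 strong regions first seen on day 7 lay at chromosome 6, 164166901 to 164167305, and chromosome 11, 13139700 to 13140129, with folds of 6.61 and 6.01. Of the same 4899 regions, 4542 (92.7%) had a peak on all 3 induced days.

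Between successive induced days the lists differed less in strong peaks. From day 1 to day 3, 20.5% (20.2 to 20.7) of the day 3 peaks were new, and 135 strong peaks were gained while 4 were lost. From day 3 to day 7 the balance turned: 12.5% (12.3 to 12.7) of day 7 peaks were new, 23.9% of day 3 peaks had no counterpart on day 7, and 5 strong peaks were gained while 83 were lost. The 4 strong peaks lost from day 1 to day 3 were led by chromosome 10, 50489477 to 50489919, with a fold of 6.60, followed by positions on chromosomes 4, 20 and 17. The 5 gained from day 3 to day 7 were led by chromosome 2, 40078591 to 40079315, with a fold of 6.76, followed by positions on chromosomes 6, 3, 5 and 11. The strong region with the highest day 3 fold among those open on days 1 and 3 only was chromosome 2, 196571199 to 196572034, with folds of 7.52 and 9.84. Among regions first seen on day 3 and kept on day 7, chromosome 5, 32852403 to 32853034, had the highest day 3 fold at 9.25, with 8.46 on day 7.

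At the 60786 regions present on every day, most summits differed little from day 0. Summit reads were scaled by the genome background of their list, and the median log2 change from day 0 was 0.08 on day 1, -0.08 on day 3 and -0.04 on day 7, with SDs over regions of 0.37, 0.43 and 0.34. Summits at least 2-fold higher than on day 0 numbered 2363, 2444 and 1352 on days 1, 3 and 7, and summits at least 2-fold lower numbered 6, 43 and 38. By the authors' fold, which divides by the local background, far fewer were at least 2-fold higher (615, 647 and 276), and 10, 54 and 21 were at least 2-fold lower. Counting error alone gave on average 54.1, 48.2 and 54.3 regions with summits at least 2-fold higher when the reads of unchanged regions were redrawn. Falls were not counted in the redrawn data, so the 6, 43 and 38 lower summits were not shown to exceed counting error. A total of 1155 regions were at least 2-fold higher on all 3 days. All 3 comparisons use the same day 0 list, which gave 5.25 such regions in the redrawn data, and independent lists of these lengths would share 2.11. Part of the excess may still come from the shared day 0 list, since its replicates could not be split.

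The regions with the highest summits relative to day 0 were also picked after their values were seen, as were those with lower summits. Their intervals do not allow for this choice among 60786 regions, so the changes may be overstated. Chromosome 4, 4811795 to 4813186, was 8.13-fold higher on day 1 (5.09 to 13.7), 8.54-fold on day 3 (5.37 to 14.3) and 5.77-fold on day 7 (3.56 to 9.81), from 20 summit reads on day 0 to 155 on day 1. Its local background was also 2.98 times that of day 0 on day 1, so its fold was only 2.85, 2.71 and 2.65 times the day 0 fold on days 1, 3 and 7. Chromosome 5, 125004395 to 125005331, was 7.70-fold higher on day 1 (5.01 to 12.3), or 4.06 times by fold, and 4.25-fold on day 7 (2.69 to 6.94). Chromosome 21, 30486838 to 30487913, was 4.45-fold higher on day 1 (2.74 to 7.54) and 7.28-fold on day 3 (4.60 to 12.1), where its fold was 3.26 times that of day 0. Chromosome 3, 67980504 to 67981870, was the highest on day 7, at 5.91-fold (3.73 to 9.76), or 3.39 times by fold. Lower summits were seen at chromosome 7, 38916123 to 38916914, which was at 0.331 of day 0 on day 3 (0.231 to 0.467) and at 0.881 on day 7 (0.678 to 1.14). Chromosome 2, 178563062 to 178564004, was at 0.352 on day 3 (0.230 to 0.528) and 0.777 on day 7 (0.559 to 1.08). Chromosome 22, 42896060 to 42897073, was at 0.354 of day 0 on day 7 (0.228 to 0.538) and at 0.761 on day 1 (0.546 to 1.06). By fold these 3 regions were at 0.663, 0.643 and 0.580 of day 0 on days 3, 3 and 7, so none was 2-fold lower on that scale.

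Gained regions stood highest on day 3. The 19074 regions gained on all 3 induced days had a median summit of 6.62 times the genome background on day 1, 8.03 on day 3 and 6.39 on day 7. The median log2 step was 0.18 from day 1 to day 3 (SD over regions 0.39) and -0.27 from day 3 to day 7 (SD 0.37), and 77.3% of these regions were lower on day 7 than on day 3. Day 3 was the highest day in 58.5% of them. The 57848 regions present on every day with under 2-fold change had a median log2 step of 0.03 from day 3 to day 7. Among the 3 induced days, day 1 was the highest in 68.6% of them, with day 0 left out of that count. The 2858 regions present on every day and at least 2-fold higher on some later day had medians of 5.36, 14.6, 15.2 and 11.3 on days 0, 1, 3 and 7. That class was selected on its height on those days. Without replicates, the size of these steps cannot be set against the spread between cultures.

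**Figure D2:**
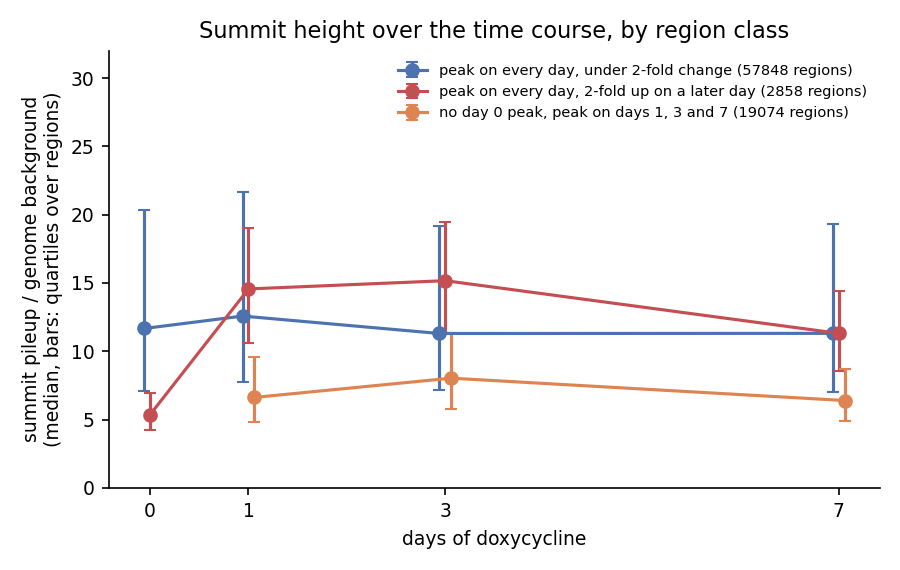
Summit reads divided by the genome background of the list (vertical axis) against days of doxycycline (horizontal axis), as the median over regions with bars from the lower to the upper quartile of regions. Gained regions (orange, 19074) had medians of 6.62, 8.03 and 6.39 on days 1, 3 and 7, and regions present on every day with under 2-fold change (blue, 57848) had 11.7, 12.6, 11.3 and 11.3 on days 0, 1, 3 and 7.

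Gained regions lay in groups along the genome more often than random draws from all merged regions did. These draws matched chromosome alone, not width, summit height or the number of lists with a peak. The excess can therefore not be credited to being gained. Joining gained regions no more than 10000 bp apart gave 15854 groups, of which 13324 held a single region, 530 held at least 3 and 21 held at least 5. When the same number of regions per chromosome was drawn at random from all merged regions 1000 times, the median was 311 groups of at least 3 and 10 of at least 5, and the highest values were 376 and 20. The largest groups, of 7 gained regions, were not unusual in size, as the largest group in the random draws had a median of 6 and a maximum of 14. They lay at chromosome 13, 97907085 to 97933117, and chromosome 5, 107132522 to 107168111, and both held 0 regions with a day 0 peak. The group on chromosome 13 spanned 26.0 kb and had 10, 10 and 8 peaks on days 1, 3 and 7. Of the 7 groups of 6 gained regions, 2 held 0 regions with a day 0 peak, at chromosome 4, 88441190 to 88456870, and chromosome 10, 14082168 to 14117111. The other 5 held between 1 and 3 such regions, among them chromosome 17, 34206806 to 34238610, and chromosome 2, 152890632 to 152925077, with 3 each. A first run with slightly longer gaps had given 720 groups of at least 3 against a median of 452 in the random draws.

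**Figure D3:**
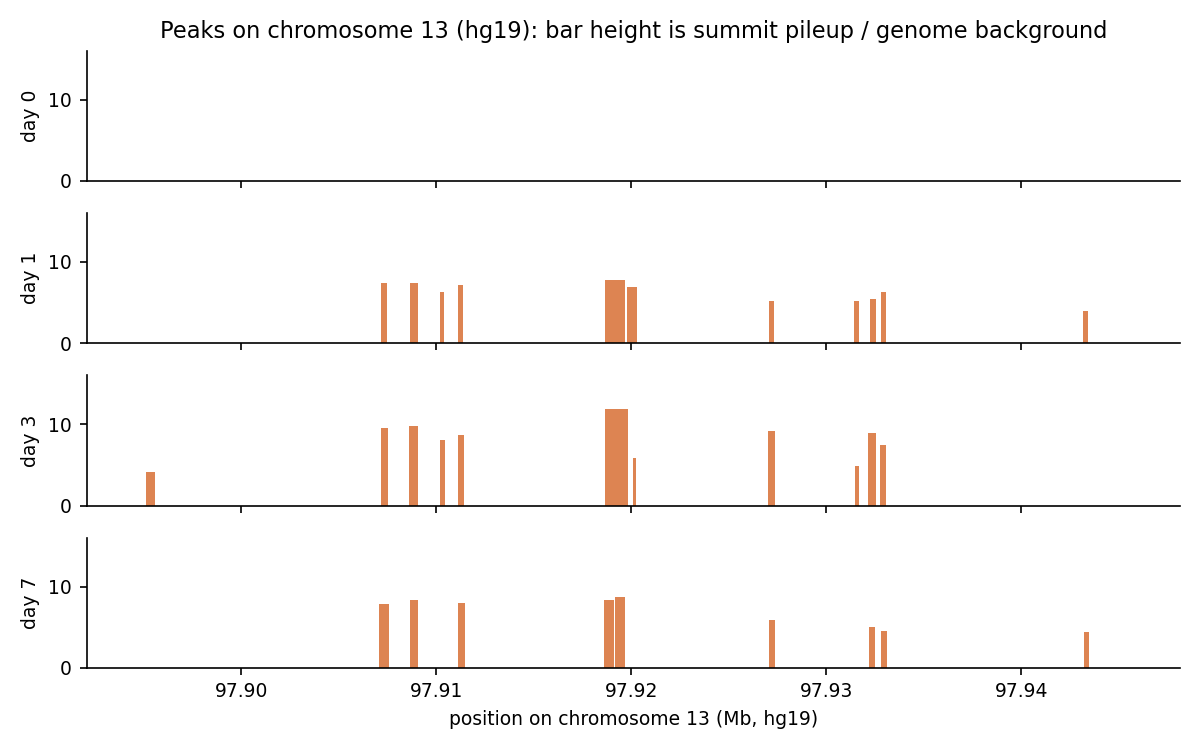
Peaks at a group of 7 gained regions on chromosome 13 (horizontal axis, Mb in hg19), with 1 panel per day. Bars span each called peak and their height (vertical axis) is the summit reads divided by the genome background; the day 0 panel is empty, and within the group itself 10, 10 and 8 peaks were called on days 1, 3 and 7, the highest at 7.78, 11.9 and 8.69.

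Chromosomes differed in their share of gained regions. The intervals treat regions as independent draws and hold no replicate error, so they may be too narrow where gained regions lie in groups. Over 23 chromosomes, with Y left out, 13.1% of 145866 merged regions were gained on all 3 induced days. Among these chromosomes the highest shares were on chromosomes 13 (15.4%, 14.2 to 16.6), 4 (15.0%, 14.1 to 15.8) and 2 (14.8%, 14.1 to 15.5). Chromosome 19 had the lowest share among them, at 6.46% (5.83 to 7.14) of 5526 regions, and 56.6% of its regions had a peak on every day. Chromosomes 22, 16 and 17 followed with 10.3% (9.31 to 11.4), 10.3% (9.50 to 11.2) and 10.5% (9.80 to 11.2).

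**Figure D4:**
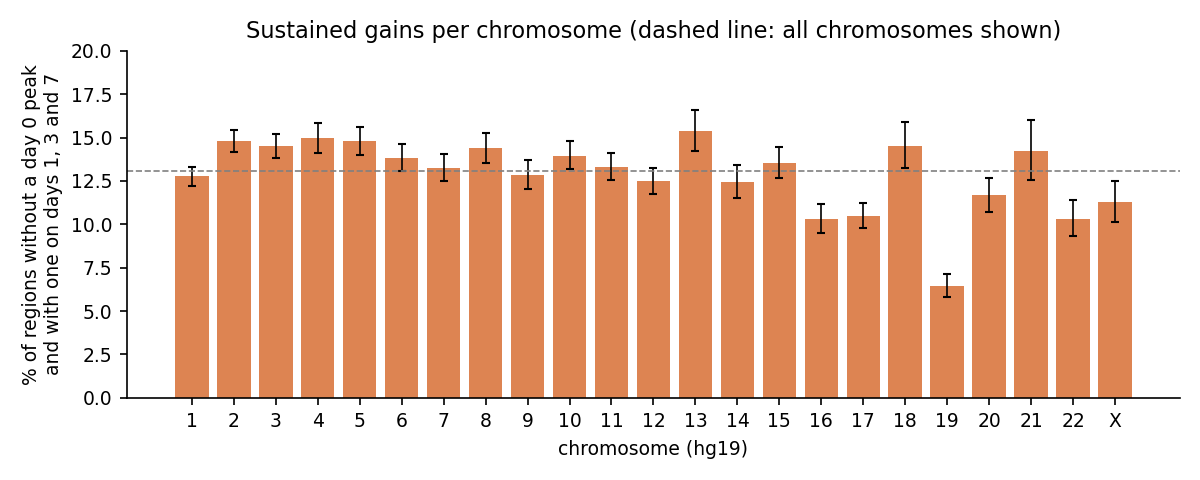
Share of merged regions without a day 0 peak and with a peak on days 1, 3 and 7 (vertical axis, percent) for each of 23 chromosomes (Y left out), with exact binomial 95% intervals as bars and the value over these chromosomes, 13.1%, as a dashed line. Among those shown, chromosome 19 has the lowest share, 6.46%, and chromosome 13 the highest, 15.4%.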

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

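No paired analysis was possible because the lists carry no replicate values. For the same reason the intended tests per region, their alternatives and the runs leaving out each replicate were not run, and those for promoter share, motif share and gene lists were not run because no hg19 genome or annotation was used here. The limits on fold, the summit limit, the common p limit, and the 50% overlap applied to strong peaks were chosen after seeing the data. Of 75 alternative values over 27 results, 33 stayed within 1.5 times of a count or length or within the interval of a share, and 42 moved. Changes of direction were not scored. A common p limit, set by the day 0 list, left 80744, 109809, 117556 and 103173 peaks on days 0, 1, 3 and 7. It moved 0 of the results it was applied to, but it removed so few peaks that it could hardly move any. Keeping only peaks at or above the median score of all lists left 41754, 54869, 59427 and 50092 peaks on days 0, 1, 3 and 7, which is lower by construction. Requiring a reciprocal overlap of at least 50%, the share of day 0 peaks kept was 78.6%, 76.5% and 75.2% on days 1, 3 and 7, the share of new peaks 42.2%, 47.5% and 41.2%, and the strong peaks lost 73, 108 and 93. With peaks at or above each list's own median score, 94.6%, 92.8% and 91.9% of day 0 peaks were kept and 30.5%, 36.9% and 28.1% were new. A fold of at least 5 gave 5023, 7805 and 4765 strong peaks gained and 33, 39 and 120 lost, and a fold of at least 7 gave 1325, 2234 and 994 gained, with 0 lost on day 3 and 2 on day 7. A summit of at least 10 times the genome background gave 5915, 7699 and 3633 gained and 947, 1138 and 1366 lost, and the cause was not tested. At regions present on every day, the authors' fold called 615, 647 and 276 at least 2-fold higher and 10, 54 and 21 at least 2-fold lower. By fold, 52.0% of gained regions were highest on day 3. Depth limits weak peaks most: with summits of 16 to 18 reads, absence from a list means only that no peak was called.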

Other observations

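All tests in this part were chosen after the results were seen. A first enrichment test left 100% of strong gains above the day 0 limit, but such peaks could hardly fail it. The enrichment comparison given below restates it with the same median shift and needed drop, so it shares that limit. Gained regions lay farther from other day 0 peaks than regions present on every day did. The median distance to the nearest other day 0 peak was 9.05 kb for the 19074 gained regions and 5.89 kb for regions present on every day, and 53.2% (52.5 to 54.0) against 66.9% (66.6 to 67.3) had such a peak within 10000 bp. Regions seen on 1 induced day alone lay between them, at 7.82 kb and 57.9% (57.4 to 58.5). Regions with a peak on day 0 alone were at 6.23 kb and 67.4% (66.2 to 68.6), close to regions present on every day. These classes were defined by having or lacking a day 0 peak, so the larger distance cannot be credited to being gained. For gained regions with a fold of at least 6 the median was 18.8 kb. Picking the same number of gained regions, 4542, by scaled summit in place of fold gave 6.78 kb, so the larger distance of the strong ones depends on ranking by fold. Local background was 1.40 times the genome-wide value at the median for the former and 2.60 times for the latter.

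The excess of strong gains over strong losses after day 0 was weighed against depth, enrichment and treatment. A shallower day 0 list would need induced lists of greater depth, yet the background of day 1 was 0.953 of day 0, and that of day 7 was 0.962, while 2558 and 2228 strong peaks were gained. The day 3 list was deeper by a log2 of 0.084, far less than the drop of at least 1.22, beyond depth, that would hide a strong day 3 gain. A day 0 library with lower enrichment overall would have lower summits at all regions. Hiding a strong day 1 gain needs a drop of at least 1.25 on the log2 scale. Regions present on every day differed by a median of 0.083 (SD 0.37), so no uniform drop of that size was seen at them. They were selected for having a day 0 peak, so they cannot show whether enrichment was lower at sites that lack that peak. Doxycycline or time in culture without SMARCB1 cannot be told apart from SMARCB1 itself, as 0 samples of an induced day are labelled SMARCB1 -/-, so restored SMARCB1 may be the source of the gains but stays a hypothesis.

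Regions present on every day whose fold was at least 2-fold lower than on day 0 numbered 54 on day 3 and 21 on day 7. On day 3 their summit reads changed by a median log2 of -0.14 (quartiles -0.34 and 0.03) and their local background by 1.03, and 4 of the 54 had a summit at least 2-fold lower. On day 7 the medians were -0.29 (quartiles -1.04 and -0.11) and 0.87, and 7 of the 21 had a summit at least 2-fold lower. All of them have a peak on every day, so sites whose peak was lost are not among them.

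Lower summits of gained regions on day 7 than on day 3 could come from higher enrichment in the day 3 list. Regions present on every day, matched on summit height in 20 bins, had a median log2 step of -0.00083 against -0.27 at gained regions, which were lower in 20 of 20 bins. No uniform fall was therefore seen at the matched regions. Their SD was 0.28, about as large as this gap, but it is a spread of single regions and not the error of a median. The 2858 regions at least 2-fold higher on some later day had a median step of -0.41, but that class was selected on its height. Without replicates the error of a step between lists is not known, so a difference in enrichment stays open. An earlier form of the test had left the 2858 regions out, and it was replaced because the change under test helped to choose its regions. No biological explanation was tested.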
